A study of Homo sapiens with 4 samples.

How the data were processed

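Total RNA of UB27 cells, a U2OS osteosarcoma line with tetracycline-repressible WT1(-KTS), was measured on 4 Affymetrix human genome oligonucleotide arrays with biotin label, 1 each for uninduced cells (0 h) and for 4, 8 and 12 h of induction. Groups and times were taken from the sample titles and descriptions. There is no replicate within a group. The titles of the induced samples end in a number that the title of the uninduced sample lacks, while all 4 titles share a date-like string. What that number stands for is not given in the sources used here, so whether the uninduced array belongs to the same series of cultures is not known.

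The deposited table holds 1 signal intensity per probe set and array, on a linear scale. MAS5 is the tool named in the submitters' processing notes. Its version, the scaling target and any masks are not given in the sources used here, and detection calls were not used here. MAS5 summarises the probe pairs of a probe set into 1 signal and scales whole arrays. The deposited intensities were all positive, from 0.2 to 32683, and the 2% trimmed means of the 4 arrays were each 500.1, so they were taken as already scaled to 1 target and used as deposited. Signals of this kind scatter widely near background, which inflates the fold changes of dim probe sets.

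Probe sets were named from the platform annotation of 2016, with symbols updated through gene numbers in a RefSeq gene table (GRCh38.p14). Of the 22215 probe sets that are not controls, 19065 had 1 gene, 1043 had several and 2107 had none in the table. Of those with 1 gene, 19059 gene numbers matched. Probe sets with several genes or none were counted but not named, and members of gene lists with no probe set of their own were not analysed here. No genome build is named for the array values, so no coordinates are given. A gene (11963 in all) was represented by its probe set with the highest mean log2 signal over the 4 arrays.

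In place of detection calls, signals below a floor of 153.2, the 40th percentile of all values, were raised to it before log2 was taken. The 15 probe sets for bacterial transcripts of the poly(A) control series had signals of at most 91.7, below this floor. The difference of log2 signal from 0 h was computed for each probe set, and those at 1 or more, or -1 or less, were counted as at least 2-fold higher or lower. A gene counted as measured if its probe set was above the floor on at least 1 array (8999 genes). No test was run on the difference of any probe set or gene, since there is 1 array per group. With this design a count of changed probe sets describes these arrays, and any fold change holds biological and technical differences between single samples.

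Fixed before the data were examined were the floor, the thresholds, 21 gene lists and the rule for named genes. The lists covered reported WT1 targets, growth factor families, signalling, cell cycle, stress, metabolism, inflammation, kidney, bone, matrix, housekeeping genes and markers of other cell types. A few genes are on several lists. Named were WT1, the 8 genes with the largest and the 8 with the smallest difference at each time, those 2-fold different in the same direction at all times (up to 8 per direction), the 5 per direction with early and with late differences only, up to 4 members per list and direction beyond 2-fold, and the measured members of the reported WT1 target lists. This gave 90 genes. A list's median difference was placed among the medians of 10000 random lists of measured genes, drawn in the same 10 bands of mean signal. One list name matched more than 1 current gene and was left out.

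To show what a shared control array gives by chance, 100 sets of 4 unchanged arrays were simulated. Residuals were resampled from the 12 h minus 8 h differences within 10 bands of signal and scaled by 1.10, so that simulated pairs differed 2-fold about as often (mean 138 probe sets) as those arrays did (129). The counting and list steps were tested on simulated data of 22215 probe sets with 200 changed ones. The changed probe sets were drawn only from bands with mean signals of 324 or more, and the lists left out the dimmest bands. Recovery among dimmer probe sets was therefore not tested. The residuals were used here without the factor of 1.10, so the number of unchanged probe sets that passed may be too low. For the 12 h comparison 98% of 3-fold changes, 56% of 2-fold changes and 18% of 1.5-fold changes passed the 2-fold size, and 88 unchanged probe sets did. The shares of 2-fold and 1.5-fold changes were 54% and 14% for 4 h and 46% and 10% for 8 h. All 20 simulated lists shifted by 0.5 on the log2 scale exceeded the 97.5th percentile, as did 8 of 100 unshifted lists beyond either end.

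Alternatives were rescaling to 1 trimmed mean, centring on the median, quantile normalization, cyclic loess, floors at the 20th and 60th percentile (signals of 47.5 and 327), no floor, counting without _x_at and _s_at probe sets, counting genes, and averaging a gene's probe sets. A count over probe sets above the floor on all 4 arrays was added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for quantile and loess normalization only.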

Results

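Gene expression was profiled during induction of WT1, the zinc finger transcription factor mutated in a subset of Wilms' tumours, in a human osteosarcoma cell line. UB27 cells are U2OS cells that carry the WT1(-KTS) isoform under a tetracycline-repressible promoter, so that the isoform is made when the drug is absent. WT1(-KTS) lacks the KTS tripeptide between zinc fingers and is the form best known as a DNA-binding transcription factor. Total RNA from uninduced cells (0 h) and from cells induced for 4, 8 and 12 h was hybridised to Affymetrix human genome oligonucleotide arrays, 1 array per time and 4 arrays in all. The comparisons were those of each induced time with the uninduced sample, which address the genes whose levels differ after WT1(-KTS) is switched on. With 1 array per time, no difference below has a replicate check, no p-value is given, and words such as higher and lower describe these 4 arrays.

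Each array reported 22283 probe sets, of which 22215 were not controls, and the 2% trimmed mean signal was 500.1 on each array. The share of probe sets above the signal floor of 153.2 was 60.3% at 0 h, 60.3% at 4 h, 59.0% at 8 h and 60.4% at 12 h. Log2 differences below were taken after raising signals under this floor to it, so a fold change against a signal below the floor is a lower bound, written as "at least". The number of arrays limits the precision. The only yardstick for scatter was the spread of the log2 difference between the 12 h and 8 h arrays, a robust SD of 0.26 over the 11762 probe sets above the floor on all 4 arrays. Its value was 0.40 among probe sets with mean signals of 169 to 224 and 0.19 in the brightest 10% of probe sets. It includes any true difference between these times.

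The arrays had similar RNA integrity controls and differed in ribosomal RNA. The ratio of the 3' to the 5' probe set lay between 0.89 and 0.92 for GAPDH and between 0.98 and 1.06 for ACTB. The signal of the 3' probe set for 18S ribosomal RNA was 2554 on the uninduced array, against 403 at 4 h, 563 at 8 h and 348 at 12 h. The 18S 5' probe set gave 1176, 44, 439 and 47 from 0 h to 12 h, so the induced arrays also differed among themselves. The 28S 3' probe set gave 1079 on the uninduced array and 146, 184 and 129 on the induced ones. All comparisons with 0 h use this single array, so the ribosomal RNA difference moves with every group of genes set against it.

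**Figure D1:**
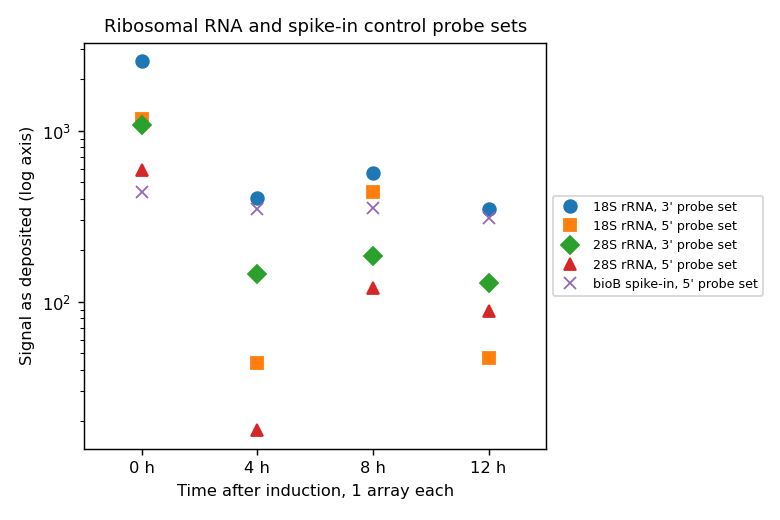
Signals of control probe sets as deposited (log axis) on each of the 4 arrays, 1 symbol per probe set. The 4 ribosomal RNA probe sets were highest on the uninduced array, with the 18S 3' signal at 2554 there and between 348 and 563 on the induced arrays, while the bioB spike-in lay between 307 and 436.

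The induced gene was examined first. One WT1 probe set (216953_s_at) had a signal of 61.5 in uninduced cells, below the floor, and 1803, 1738 and 1878 at 4, 8 and 12 h. WT1 signal was therefore at least 11.8-fold higher at 4 h, at least 11.3-fold higher at 8 h and at least 12.3-fold higher at 12 h. It was level across the induced arrays, with a log2 difference of 0.06 between 12 h and 4 h. The other WT1 probe set (206067_s_at) did not show this, with signals of 180, 209, 206 and 131 from 0 h to 12 h.

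At 4 h of induction, the genes with the largest positive differences after WT1 were HBEGF, ARC, CSF1, TBX3, RGS4, GEM and SH2B2. HBEGF, a ligand of the epidermal growth factor receptor, had a signal of 449 at 0 h and 4477 at 4 h, a 9.98-fold difference, and its second probe set above the floor had log2 differences of 1.96 at 4 h, 0.56 at 8 h and 0.12 at 12 h. ARC, an immediate-early gene, was 7.65-fold higher, CSF1, the macrophage colony-stimulating factor, 5.26-fold higher and the T-box transcription factor TBX3 4.94-fold higher. The other CSF1 probe sets above the floor on any array were below it at 0 h and had log2 differences of at least 0.18 and 0.88, and the mean over all CSF1 probe sets was 0.86. RGS4, a regulator of G protein signalling, was 4.76-fold higher, with its other probe sets at log2 differences of at least 2.16 and of 1.87, and GEM, a Ras-related GTPase, was 3.80-fold higher. SH2B2, an adaptor of receptor tyrosine kinases, was at least 3.68-fold higher. PRKCD, a protein kinase C, was 3.39-fold higher and HIVEP3 (an _x_at probe set) at least 3.27-fold, and both were below the floor at 12 h. In all, 147 probe sets were at least 2-fold higher and 95 at least 2-fold lower at 4 h, and the dimmer array was below the floor for 40 and 34 of these. With the floor at the 60th percentile of all values the counts were 58 and 27, and with no floor 1373 and 1466.

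Inflammatory genes were higher together at 4 h. All 13 measured members of the NF-kappaB and inflammatory list had positive differences, 6 of them of at least 2-fold and none lower by 2-fold, and their median log2 difference of 1.00 lay above all 10000 random lists of the same size and signal. CCL2, a monocyte chemoattractant, was 3.47-fold higher, the cytokines IL11 and LIF were 2.99-fold and 2.38-fold higher, and the adhesion molecule ICAM1 was 2.29-fold higher. NFKB1 and NFKBIA, which encode a subunit of NF-kappaB and its inhibitor, had log2 differences of 1.04 and 1.06 (these members were picked after their values were seen). By 8 h the list's median was 0.23, at the 99.8th percentile of random lists, and at 12 h it was 0.00. CCL2 was 1.06-fold of its uninduced level at 8 h and at least 1.72-fold lower at 12 h, while ICAM1 was 1.88-fold higher at 12 h on its brightest probe set, the others being below the floor. IL11 was 2.61-fold higher at 12 h on its brightest probe set and 1.41-fold higher on the other, which had been 4.78-fold higher at 4 h.

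The immediate-early and MAPK feedback list showed a smaller difference at 4 h. Of its 19 measured members, 4 were at least 2-fold higher and none 2-fold lower, with a median log2 difference of 0.28 at the 99.98th percentile. SPRY2, an inhibitor of receptor tyrosine kinase signalling, was at least 2.82-fold higher, the phosphatase gene DUSP5 2.66-fold, the AP-1 component FOSL1 2.38-fold and the stress-responsive gene IER3 by a log2 difference of 1.01. The median was 0.30 at 8 h (99.99th percentile), with no member beyond 2-fold, and -0.08 at 12 h. At 8 h 10 members had positive and 8 negative differences, against 15 and 4 at 4 h. The 8 h median was the value of SPRY1, with the next lower value, that of SPRY2, at 0. Relative to 4 h, the list's median at 8 h was -0.29. DUSP5, FOSL1 and IER3 were between 0.84-fold and 0.94-fold of the uninduced level at 12 h, and SPRY2 was below the floor at 0, 8 and 12 h.

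Mitotic genes were lower at 4 h. Of the 25 measured genes of the G2/M list, 24 had negative differences, 7 of them by 1.5-fold or more, and the median of -0.38 lay below all 10000 random lists. AURKA, a mitotic kinase, was the single member at least 2-fold lower, with a signal of 1616 at 0 h and 788 at 4 h, and its next brightest probe set had a difference of -0.73. TTK and CDC25C, both regulators of mitosis and picked after their values were seen, had differences of -0.93 and -0.69. CKAP2, a cytoskeleton-associated protein of dividing cells that was on no list, was 2.84-fold lower at 4 h and 1.06-fold lower at 12 h. The G2/M median was -0.11 at 8 h (1.2nd percentile) and 0.19 at 12 h (99.98th percentile), when 22 of the 25 genes had positive differences. The G1/S list had medians of 0.03, -0.05 and -0.01 at the 3 times, inside the range of random lists, with none of its 23 members 2-fold different.

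Other genes with the largest decreases at 4 h belonged to no common list. PAGR1 was at least 3.14-fold lower, CZIB 2.96-fold, ATP8B1 2.89-fold, AXIN1, a scaffold of the beta-catenin destruction complex, 2.84-fold, HSP90B1 2.77-fold, ASB13 at least 2.69-fold and the antiproliferative gene TOB1 2.68-fold. GOLPH3L, at least 2.61-fold lower, and ARMCX1, 2.53-fold lower, also belonged to the genes lower at 4 h and within 1.5-fold of uninduced at 12 h. ATP8B1 and HSP90B1 rest on probe sets of the cross-hybridising type (_x_at), and the second HSP90B1 probe set differed by only 0.04. The unfolded protein and amino acid response list had a median of -0.21 (0.08th percentile), with 1 of 20 members 2-fold lower, the glutathione-degrading enzyme CHAC1, whose signal was 428 at 0 h and 193 at 4 h. Other list members beyond 2-fold at 4 h included IFIT1 of the interferon list, at least 2.55-fold lower, ZMAT3 of the p53 list, 2.19-fold lower, HMGCS1 of the cholesterol list, 2.15-fold higher, and INHBA, the activin A subunit, 2.67-fold higher.

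At 8 h, HSPA6 had the largest difference after WT1. HSPA6, the strictly stress-inducible HSP70 gene, had signals of 108 at 0 h, 151 at 4 h and 1058 at 8 h, at least 6.91-fold higher, and its second probe set was at least 2.09-fold higher at 4 h and at least 2.79-fold higher at 8 h. The brighter probe set was at least 5.10-fold higher at 12 h. Of the 11 measured heat shock genes of the 14 on the list HSPA6 was beyond 2-fold at 8 h, and the co-chaperone DNAJB1, picked after its value was seen, had a difference of 0.93. The list's median was 0.05 at 8 h (81.4th percentile), inside the range of random lists, and 0.15 at 12 h (98.3rd percentile). Probe sets 200800_s_at and 202581_at, each assigned to several genes that include 2 members of this list, were picked after their values were seen, were left out of the list and had differences of 1.65 and 1.72 at 8 h. A total of 90 probe sets were at least 2-fold higher and 54 at least 2-fold lower at 8 h, against 35 and 9 with the floor at the 60th percentile and 1132 and 1474 with no floor.

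The other genes with the highest differences at 8 h were largely carried over from 4 h or dim. HBEGF was 3.07-fold higher and SH2B2 at least 3.48-fold. SLC2A3, a glucose transporter, was at least 3.19-fold higher on an _x_at probe set, while its other probe sets had differences of -0.11 or lower and of -0.18. AATK and RUSC2 were at least 2.86-fold and 2.84-fold higher from signals below the floor at 0 h, and AATK was below the floor again at 12 h. SFTPB was at least 2.77-fold higher on an _x_at probe set, and by 0.27 on the log2 scale on its second one. Among the lowest, NUDT2 was at least 2.86-fold lower, IFNA17 (an _x_at probe set) 2.83-fold, LINC00216 2.58-fold, the inner nuclear membrane protein LEMD3 2.53-fold, BAZ2B 2.35-fold, RBL2, a retinoblastoma family member, 2.26-fold, GNAO1 at least 2.24-fold and CLDN15 at least 2.20-fold. The second probe sets of RBL2 and GNAO1 gave -0.09 and at least 0.24. The unfolded protein list was still low at 8 h (median -0.15, 0.49th percentile, no member beyond 2-fold).

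At 12 h, PODXL, which encodes the podocyte sialomucin podocalyxin, and several other genes reached their highest level. PODXL signal was 736, 1034, 1604 and 2028 at 0, 4, 8 and 12 h, that is 1.41-fold, 2.18-fold and 2.76-fold of the uninduced level. ID4, an inhibitor of basic helix-loop-helix factors, was 2.17-fold higher at 8 h and 2.69-fold higher at 12 h, and its second probe set above the floor was higher by 0.42 at 12 h. NPPB, the natriuretic peptide B precursor, was at least 3.21-fold higher, and IRF2BP1 2.68-fold. SLC2A3 was at least 3.42-fold higher on the _x_at probe set, while its other probe sets had differences of -0.11 or lower and of -0.46, and the mean over its probe sets was 0.40. In all, 106 probe sets were at least 2-fold higher and 61 at least 2-fold lower, against 27 and 11 with the floor at the 60th percentile and 1248 and 1390 with no floor. Among the lowest, NUMA1, a spindle pole protein, was at least 4.89-fold lower, CDYL at least 3.61-fold, AXIN1 at least 3.23-fold, AEN, a p53-induced nuclease, at least 3.19-fold, PAGR1 at least 3.14-fold, DBF4, an activator of the S-phase kinase CDC7, 3.10-fold, CCN2 2.81-fold and ASB13 at least 2.69-fold. ESM1 (an _x_at probe set) was at least 2.64-fold lower and HOXD1 2.57-fold. The second probe sets of NUMA1 and CDYL went in the other direction, by 0.09 and by at least 0.39.

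At 12 h, CCN2 and THBS1, which encode matrix-associated proteins, were lower. CCN2, the connective tissue growth factor, had signals of 3274 at 0 h, 2469 at 4 h, 2276 at 8 h and 1167 at 12 h. THBS1, which encodes thrombospondin 1, was 2.25-fold lower at 12 h and its other bright probe sets had differences of -0.37 and -0.66, while a dimmer one had 0.10. They belong to the BMP, TGF-beta and matrix list, of which 2 of 29 measured members were 2-fold lower and 1 was 2-fold higher, SMAD6, an inhibitory SMAD (2.24-fold, second probe set -0.21). The list's median was -0.12, at the 0.84th percentile, and 26 of the 29 members passed neither 2-fold threshold.

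The 14 probe sets at least 2-fold higher at 4, 8 and 12 h included those representing WT1, HBEGF, SH2B2, SFTPB, L1CAM, DIP2C and SNAI2. SNAI2, the transcriptional repressor Slug, was 3.17-fold, 2.58-fold and 2.03-fold higher, and the adhesion molecule L1CAM 2.37-fold, 2.10-fold and 2.20-fold. The second DIP2C probe set had log2 differences of 0.57, -0.39 and 0.25, and the second HBEGF probe set was within 1.5-fold of uninduced at 8 h and 12 h. The 5 probe sets lower at all times were those of CLDN15, AXIN1, PAGR1, ZFP30 (an _x_at probe set) and NSG1, the last named after its values were seen. This NSG1 probe set was below the floor at 4, 8 and 12 h, and a brighter one, of the _x_at type, had positive differences of 0.54, 0.54 and 0.40. The control array, with its higher ribosomal RNA signal, is shared, so chance alone gives such overlaps. In 100 simulations of 4 unchanged arrays that scatter as the 12 h and 8 h arrays do, a mean of 5.2 probe sets (highest 11) were higher at all times and a mean of 8.5 (highest 16) were lower. The control could not be split, so a part of the excess of higher probe sets that comes from it was not measured.

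The overlaps between pairs of times were larger than simulated for the higher probe sets and not for the lower ones. Of the probe sets at least 2-fold higher, 29 were shared by 4 h and 8 h, 26 by 4 h and 12 h, and 35 by 8 h and 12 h. The simulated means were 9.8, 10.3 and 9.9, and independent lists of these sizes would share 0.60, 0.70 and 0.43. Of the lower ones, 12, 10 and 11 were shared, against simulated means of 15.7, 15.6 and 15.5. Of the probe sets 2-fold higher at 4 h, 94 were less than 1.5-fold higher at 12 h on floored signals, and of those 2-fold higher at 12 h, 61 were less than 1.5-fold higher at 4 h. The simulated single lists held a mean of 67.0 to 69.9 higher probe sets, fewer than the 147, 90 and 106 observed. They held a mean of 67.9 to 69.3 lower ones, against 95, 54 and 61. The observed lower counts at 8 h and 12 h lay below these means. The simulated scatter may thus be too wide for these times, and it cannot exclude an excess of lower probe sets. For 4 h it may be too narrow. The robust SD over probe sets above the floor on all arrays was 0.29 between 4 h and 0 h, against 0.26 between 12 h and 8 h. Simulated counts and overlaps that include 4 h may therefore be too low, and wider scatter of the 4 h array is not excluded as a source of the excess there. The simulation was run with the floor of 153.2 only.

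**Figure D2:**
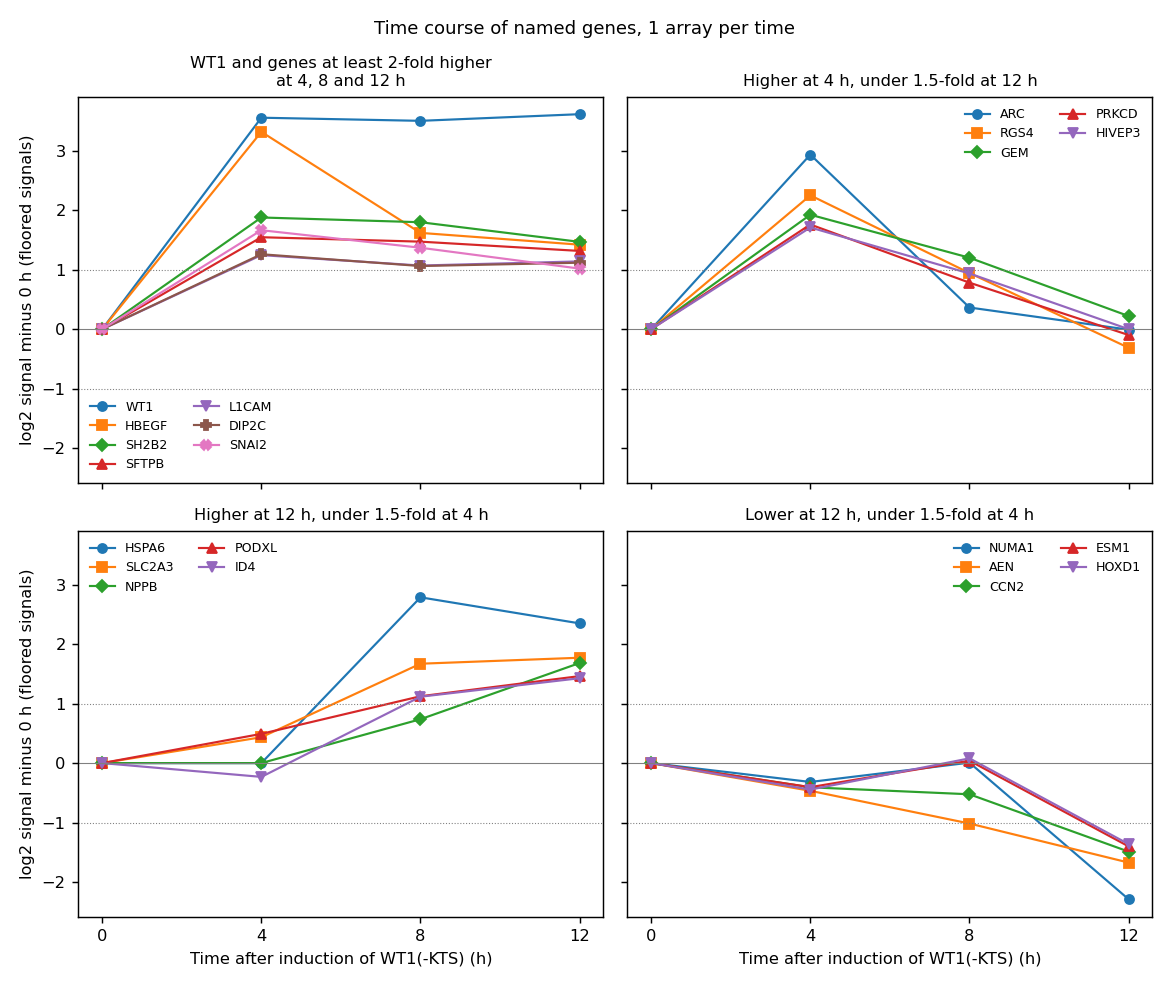
Log2 signal minus that at 0 h (vertical axis, floored signals) against time of induction in hours, 1 line per gene and 1 array per time, with dotted lines at 2-fold. WT1 was at 3.56 at 4 h and 3.62 at 12 h, ARC at 2.94 at 4 h and -0.01 at 12 h, and PODXL and ID4 reached 1.46 and 1.43 at 12 h.

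Genes earlier reported as WT1 targets were followed as lists written from general knowledge before the data were examined, and whether any of them entered that literature through these arrays was not checked. Of 22 genes reported as activated, 17 had a probe set of their own and 11 were measured. The unmeasured ones, among them HSPA1A of the heat shock list, were not assessed. HSPA1A had no probe set of its own. Probe sets 200800_s_at and 202581_at, which each include 2 heat shock list members, had differences of -1.14 and -0.58 at 4 h. At 8 h they had 1.65 and 1.72, and at 12 h 1.87 and 1.755, so a higher HSPA1A signal at these later times is not excluded. Of the 11 measured genes, 1 was at least 2-fold higher at each time. At 4 h it was BMP7, a kidney morphogen, whose brightest probe set was at least 2.45-fold higher, though its other probe sets above the floor had differences of at least 0.02 and of 0.14. At 8 h and 12 h it was PODXL. The list's median was 0.00, 0.22 and 0.15, the 8 h value lying at the 99.2nd percentile. NES, which encodes the intermediate filament nestin, was 1.76-fold higher at 12 h, and the cell cycle inhibitor CDKN1A was 1.00-fold, 1.27-fold and 1.17-fold of its uninduced level. The remaining members (SPRY1, VDR, SDC1, BCL2A1, RBBP7, ITGA8 and ETS1) had log2 differences of floored signals between -0.76 and 0.68 at all times on their brightest probe sets. The other VDR probe set above the floor on any array was below it at 0 h and 12 h. It had differences of at least 0.74 at 4 h and 0.56 at 8 h, against -0.23 and 0.22 on the brightest.

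Of 18 measured genes reported as repressed by WT1, none was 2-fold lower at 4 h or 8 h and 3 were at 12 h, when 1 was 2-fold higher, CSF1 (2.22-fold). The lower ones were CCN2, THBS1 and MYB, a proto-oncogene that was 2.02-fold lower from a signal of 313. EGFR, the epidermal growth factor receptor, had a log2 difference of 0.54 at 4 h and -0.81 at 12 h, and its second bright probe set 0.05 and -0.77, while a dimmer one had 0.66 and 0.17. MYC had 0.46 and -0.79. At 4 h the list went the other way, with a median of 0.50 above all 10000 random lists and 3 members at least 2-fold higher: CSF1, the retinoic acid receptor RARA (2.86-fold) and PDGFA, a platelet-derived growth factor chain (a log2 difference of 1.01). The other PDGFA probe set above the floor had 0.15 and that of RARA at least 0.86. IGF1R, EGR1, JUNB, INHA and CCNE1 had differences of 0.74, 0.88, 0.94, at least 0.53 and 0.58 at 4 h. The 4 h median lay between MYC at 0.46 and INHA at 0.53, with TGFB1 next below at 0.13. EGR1, JUNB and MYC are also on the immediate-early list, so the medians of these lists are not independent. The WT1-repressed list's median was 0.05 at 8 h and -0.03 at 12 h. ODC1, TGFB1, MDK and ABCB1 had differences between -0.24 and 0.15 at all times, and PAX2, dim throughout, was below the floor at 4 h.

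**Figure D3:**
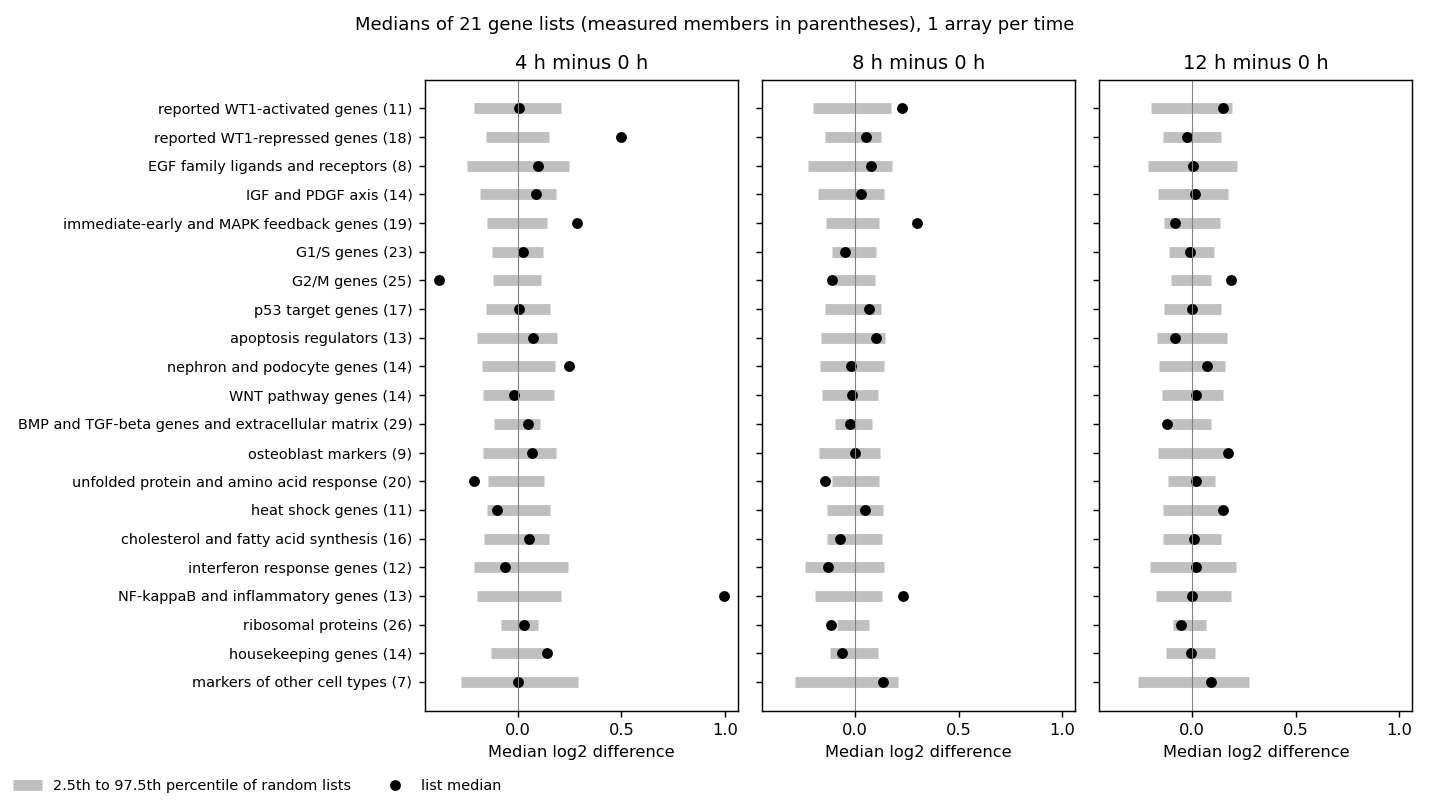
Median log2 difference from 0 h (horizontal axis) of 21 gene lists at 4, 8 and 12 h (points), with the range that holds the middle 95% of the medians of 10000 random lists matched on size and signal (grey bars). The NF-kappaB and inflammatory list at 1.00 and the reported WT1-repressed list at 0.50 stand farthest above their bars, both at 4 h. The WT1-repressed list shares EGR1, JUNB and MYC with the immediate-early list. The G2/M list at -0.38, also at 4 h, stands farthest below.

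Of the 63 combinations of list and time, 17 lay beyond the range of random lists. At a rate of 5%, 3.15 would be expected if genes within a list varied independently, while 8 of 100 unshifted simulated lists lay beyond. Some lists share members, and all use the uninduced array with the higher ribosomal RNA signal. Beyond those described above, they were the nephron and podocyte list at 4 h (median 0.24, 99.6th percentile, BMP7 the only one of 14 members 2-fold higher), housekeeping genes at 4 h (0.14, 98.1st percentile), ribosomal protein genes at 8 h (-0.12, 0.29th percentile) and osteoblast markers at 12 h (0.17, 97.9th percentile), with no member of the last 3 lists beyond 2-fold. The 9 lists never beyond the range were the EGF family, the IGF and PDGF axis, G1/S genes, p53 targets, apoptosis regulators, WNT pathway genes, cholesterol and fatty acid synthesis, interferon response genes and markers of other cell types. Their medians lay between -0.13 and 0.14, and of their 124 measured memberships 3 were 2-fold higher and 2 lower at 4 h, 1 and 0 at 8 h, and 2 and 0 at 12 h. Among markers of other cell types, PECAM1, an endothelial marker, was 2.02-fold higher at 12 h, from 179 to 361, while its other probe sets were below the floor on all arrays.

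Comparisons among the induced arrays, which do not use the uninduced array, placed the 4 h array apart. The 18S 5' ribosomal RNA signal also differed among these arrays, at 44, 439 and 47 for 4, 8 and 12 h. Between 8 h and 4 h, 235 probe sets differed by at least 2-fold, between 12 h and 4 h 321, and between 12 h and 8 h 129. The corresponding totals against 0 h were 242 at 4 h, 144 at 8 h and 167 at 12 h. Over probe sets above the floor on all arrays, the robust SD of the log2 difference was 0.30 for 8 h and 4 h, 0.31 for 12 h and 4 h, and 0.26 for 12 h and 8 h. Relative to 4 h, the NF-kappaB and inflammatory list had a median of -0.69 at 8 h and -0.54 at 12 h, and the G2/M list 0.24 and 0.56.

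Different probe sets for the same gene on the same array gave a partial check. Among the 87 genes at least 2-fold higher at 4 h, 35 second probe sets were above the floor, and 30 of them had a positive difference and 14 one of at least 1.5-fold. At 12 h these numbers were 17 and 8 of 24, and at 8 h 12 and 1 of 17. For genes 2-fold lower, 11 of 17 second probe sets were lower at 4 h, 4 of 7 at 8 h and 6 of 13 at 12 h, and 6, 0 and 2 of these were lower by at least 1.5-fold.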

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

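The tests of explanations in this part were chosen after the result was seen, except that both scalings used had been planned. CREB3L1, a membrane-bound transcription factor gene outside the rule for named genes, was flagged because it differed from 0 h by at least 2-fold in opposite directions at different times, with log2 differences of -1.41 at 4 h, 1.01 at 8 h and 1.06 at 12 h. Its signal at 4 h was below the floor. It rests on 1 array per time, and the difference between times was not tested.

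The first pattern weighed is the higher signal of inflammatory and immediate-early genes at 4 h, with a median log2 difference of 0.64 over the 32 measured genes of both lists. Scatter of single probe sets on the 4 h array as the whole cause is argued against by 16 second probe sets of these genes, whose median was 0.27 (99.9th percentile of random second probe sets) with 14 of 16 higher. ICAM1 gave 2 of these, so they are not all independent and the percentile may be too extreme. A response in proportion to the WT1 signal as the whole cause is argued against by a median of -0.55 between 12 h and 4 h, with 27 of 32 genes lower, while WT1 differed by 0.06. This contrast reuses the 4 h values that marked out the pattern, so it is not an independent check. Handling of the cells when tetracycline was withdrawn, such as a change of medium, cannot be told apart from an early response to WT1 because no array of cells handled without induction is among the 4 (median at 4 h 0.64). A departure of the 4 h sample as a whole stays open too, since second probe sets read the same RNA.

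The second pattern is the lower signal of G2/M genes at 4 h. Scatter of single probe sets is argued against by a median of -0.33 over 16 second probe sets, 12 of them lower (0.03rd percentile). AURKA gave 2 of these, so here too they are not all independent and the percentile may be too extreme. Scaling of the array as the whole cause is argued against by medians of -0.39 under quantile normalization and -0.38 under cyclic loess, which correct shifts that depend on signal. A different mix of cell cycle stages in the cells harvested at 4 h, with G1/S genes at a median of 0.025, may account for it, but whether WT1 or the handling set that mix cannot be told apart with these samples. A departure of the 4 h sample as a whole stays open here too.

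The third pattern is the higher ribosomal RNA signal on the uninduced array. If that array had labelled more RNA without poly(A) tails in general, histone genes should be lower on all induced arrays. The medians of 14 measured histone genes were -0.061, 0.059 and -0.0275 at 4, 8 and 12 h, all inside the range of random lists. Some histone transcripts carry poly(A) tails and 14 genes are few, so this possible explanation stays open. No biological explanation was tested.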

How the results depend on the processing

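No paired analysis was possible because each time has 1 array. The counts of 2-fold probe sets depend on the floor and on what is counted, and the cause was mostly construction (more dim values or fewer probe sets). Higher and lower counts are given as pairs for 4, 8 and 12 h, then the counts between 8 h and 4 h, 12 h and 4 h, and 12 h and 8 h. With the floor at the 20th percentile they were 658 and 685, 528 and 595, 606 and 617, then 1402, 1546 and 1173. With no floor they were 1373 and 1466, 1132 and 1474, 1248 and 1390, then 2943, 3080 and 2709, so more probe sets were lower than higher, as with the lower floor. With the floor at the 60th percentile they were 58 and 27, 35 and 9, 27 and 11, then 73, 112 and 23. Without _x_at and _s_at probe sets they were 76 and 60, 41 and 28, 55 and 29, then 121, 166 and 62. Counting genes gave 87 and 59, 47 and 31, 51 and 34, then 131, 179 and 69. Over probe sets above the floor on all 4 arrays, an alternative chosen after seeing the data, the values that moved by over 1.5 times were 59 lower at 4 h, 28 lower at 8 h, 63 higher and 24 lower at 12 h, then 146, 199 and 68. The 4 scalings left each count within 1.5 times, and rescaling to the trimmed mean or the median moved almost nothing because the arrays already nearly shared both. The WT1 log2 difference at 4, 8 and 12 h was 4.87, 4.82 and 4.93 with the lower floor and with none, 2.46, 2.41 and 2.52 with the higher floor, and 1.89, 1.85 and 1.69 averaged with its second probe set. Of the 107 named gene values beyond 2-fold, 100 stayed there under cyclic loess, 105 under quantile normalization, 43 with the higher floor and 69 after averaging a gene's probe sets, and none changed sign. Of 546 alternative medians of lists, 55 moved by more than the SD of the random medians, besides the 4 reversed ones below. Medians of lists kept their direction where they stood apart, except when 4 h replaced 0 h as baseline. There the 8 h medians were -0.29 for immediate-early genes, 0.24 for G2/M genes, 0.12 for the unfolded protein list and -0.69 for inflammatory genes. This is a different contrast and not a change of processing. Medians from 0 h went from -0.38 at 4 h to -0.11 at 8 h for G2/M genes, -0.21 to -0.15 for the unfolded protein list and 1.00 to 0.23 for inflammatory genes, so their departure at 4 h was larger. For immediate-early genes they were 0.28 and 0.30. Why the lists differed between these times was not tested. Signal over background sets a limit, since a gene below the floor on 1 array has only a bound on its fold change.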

Other observations

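The genes and probe sets of this part were picked after their values were seen, and nothing was tested on them. Within the fixed lists, members short of 2-fold included XBP1, a transcription factor of the unfolded protein response, with log2 differences of -0.995, -0.22 and -0.05 at 4, 8 and 12 h. The cystine transporter gene SLC7A11 had -0.65, -0.46 and -0.35. ACTN4, which encodes the podocyte actin crosslinker alpha-actinin-4, had 0.82, 0.58 and 0.48. NRG1, a ligand of the ERBB receptors, had -0.83, -0.50 and -0.53, against 3.32, 1.62 and 1.42 for HBEGF of the same list.

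Some of the largest differences fell on probe sets that the annotation assigns to several genes and that are therefore not named. Probe set 200800_s_at had signals of 1876, 851, 5895 and 6849 from 0 h to 12 h, and 202581_at had 1329, 887, 4383 and 4486. Probe set 214870_x_at, assigned to 7 genes, was higher by log2 values of 2.03 at 8 h and 1.92 at 12 h, and 221501_x_at, assigned to 7 genes, by 1.44 and 1.55. Probe set 215499_at was higher by 1.26 at 4 h and had a difference of -1.98 or lower at 12 h, when it was below the floor.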
